A study of Gallus gallus with 21 samples.

How the data were processed

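Messenger RNA was sequenced from the trunk part of the neural tube of 21 chick embryos, 9 in the control group (CTRL) and 12 in the group in which MOXD1 was targeted with CRISPR/Cas9 (KO). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, constructs were electroporated into the neural tube on one side, so that a library can hold edited and unedited cells; the share of edited cells and the kind of control construct are not given in the sources used here. Libraries were made from 50 ng of total RNA with a stranded poly(A) kit and 14 cycles of final PCR, per the labels' protocols. No molecular identifiers are named, so counts of fragments need not be independent molecules, and the intervals on shares cover counting error only. The series design counts the samples as embryos, and no batch, sex or pairing of embryos is stated in the labels.

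The deposited table held raw counts of fragments per gene, 1 column per library, together with the exon length of each gene in bases. Per the file headers, counts were made by the authors with featureCounts 2.0.1 over exons grouped by gene, on the Ensembl annotation of the GRCg6a chicken assembly, release 101, with fragments of read pairs counted on the reverse strand and without the options that count multi-mapping or multi-overlapping reads. Reads shared by overlapping genes on the same strand, or by near-identical gene copies, were therefore left out of the counts. Per the submitters' processing notes, bcl2fastq, FastQC, STAR, MultiQC and DESeq2 were also used on the GRCg6a build; their versions and settings are not given in the sources used here. No other column of values per library was present (0 columns).

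Total counts ran from 16164404 to 21133788 per library. The table listed 24356 genes, of which 20966 had at least 1 count in any library and 13809 passed the filterByExpr function of edgeR 4.0.16 (R 4.3.3). The groups were compared with edgeR's quasi-likelihood F test on these counts with TMM factors and group as the only term, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on adjusted p. Fold changes are KO over CTRL, standard errors were derived from the fitted coefficient and its F value, and CPM values, counts scaled to a common library size, used TMM-scaled library sizes. Single values per library were compared by exact permutation over all 293930 splits of the 21 libraries, 2-sided, in a family of 10 measures with Benjamini-Hochberg adjustment. Principal components were computed on log2 CPM of autosomal genes.

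The plan made before the data were examined was to test MOXD1 itself and 43 lists of named genes. The gene IDs of the table were not paired with symbols in the table, and 0 of the 24356 IDs matched the RefSeq gene list of another assembly given for chicken, so the MOXD1 level and the 43 lists were not analysed here. Groups of genes by chromosome, chosen after the data were seen, took their place: the 35 chromosomes or scaffolds with at least 10 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted over the 35 groups, with camera using an estimated correlation and fry beside it. The planned rule for named genes asked for genes past the threshold that had a symbol and, where too few passed, for the genes with the smallest unadjusted p in each direction, with a mean of at least 1 CPM and a value on the same side of the CTRL median in at least 9 of the 12 KO libraries. The rule was applied without the symbol and with fewer genes than the plan allowed. Only the 2 genes with the smallest p in each direction are named, by their IDs.

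The test was tried on simulated counts drawn from the means and library sizes of the real libraries, in 5 runs with 200 changed genes among 13809 each. Changed genes were drawn only from genes with a mean of at least 1 CPM, so the shares called do not cover genes below it. For the comparison of KO with CTRL, the share of changed genes called was 39.4% at 1.5-fold, 72.8% at 2-fold and 95.8% at 4-fold, and 33 of 68045 unchanged genes were called. Each run mixed changes of these sizes, and the adjusted p of a gene depends on all of them. The share at 1.5-fold therefore need not hold where all changes are that small. Changes were planted for the whole library, so the shares do not cover changes limited to edited cells. In the same runs camera called 5 of 5 planted groups of 60 genes and 0 of 150 unchanged groups. Genes were simulated as independent, so this does not show how often camera calls unchanged groups of correlated genes; in random splits of the real libraries its preset correlation called at least 1 chromosome group in 82 of 100, the real split included. Libraries of one group were compared in pairs over genes with at least 20 counts; the lowest chi-square per degree of freedom was 29.2, so no pair agreed within sampling noise.

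Alternatives fixed before the data were examined were median-of-ratios and upper-quartile factors, no filter beyond 1 count, a filter of 1 CPM in 9 libraries, DESeq2 1.42.0, limma voom with quality weights, robust edgeR, the summed log2 CPM of W genes as covariate, 1 or 2 surrogate variables (sva 3.50.0), genes on Z and W left out, the replicate number in the title or in the description as a block, an adjusted p under 0.1, a change of at least 1.5-fold, and each library left out in turn. Added after the data were seen were the log2 W share as covariate, the count of genes at an unadjusted p under 0.05, fits without CTRL replicate 1 and KO replicate 8, which stood apart from the other 19 libraries, and such fits with a covariate. Also set after the data were seen were the W share of 0.1% that separates libraries with and without W transcripts, and the rules for missing genes (a median of at least 10 CPM in the other 19 libraries and at most a 32nd of it in the library) and high genes (at least 10 CPM and 8 times that median). Results were compared with 100 random splits of the libraries into 9 and 12.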

Results

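RNA sequencing counted transcripts in the trunk neural tube of 9 control chick embryos (CTRL) and 12 embryos in which MOXD1 was targeted by CRISPR/Cas9 (KO). The neural tube is the forerunner of the spinal cord, and neural crest cells leave its dorsal side; MOXD1 encodes a protein related to the copper-dependent enzyme dopamine beta-hydroxylase. Total counts ran from 16164404 to 21133788 in CTRL and from 16346238 to 20970382 in KO libraries, with group means that differed by less than the SD within either group (exact permutation p = 0.487). Between 12473 and 13099 genes per library reached 1 CPM. The group means were 12832 ± 177 genes (SD, n = 9) in CTRL and 12700 ± 113 (SD, n = 12) in KO, which did not pass the exact permutation test (p = 0.0516, adjusted p = 0.258 over 10 measures).

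The comparison asked which transcripts differ in the trunk neural tube when MOXD1 is targeted before neural crest cells commit to a lineage. No single gene passed the threshold, and the 4 genes named by the rule stood at 0.280 to 1.71 times the control level. ENSGALG00000052557 stood at 27.3 CPM ± 5.62 (SD, n = 12) in KO and 19.3 CPM ± 2.29 (SD, n = 9) in CTRL, above the CTRL median in 11 of 12 KO libraries. ENSGALG00000015055 stood at 0.949 CPM ± 0.351 (SD, n = 12) in KO and 2.57 CPM ± 1.57 (SD, n = 9) in CTRL, below the CTRL median in 12 of 12 KO libraries. CTRL replicates 1, 2 and 7 stood at 4.67, 4.85 and 4.21 CPM. The other controls lay at 0.833 to 2.39 CPM, a range that overlaps the 0.549 to 1.71 CPM of KO. The rule for naming a gene required at least 9 KO libraries on one side of the CTRL median. The level of MOXD1 was not analysed here, because the gene IDs of the table were used without symbols.

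Of 13809 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.675. DESeq2 also called 0 genes, with a smallest adjusted p of 0.0867. At an unadjusted p under 0.05, edgeR listed 977 genes, where chance alone would list 690 on average. Where genes vary together, a count by chance can lie far from that average. With the summed log2 CPM of W genes as covariate edgeR listed 543 genes, and the count ran from 452 to 1705 over the alternative fits. An excess over 690 was thus not found in every fit. DESeq2, which tested 20966 genes, listed 1330. Of the 977 genes, 356 were higher and 621 (63.6%) were lower in KO, a share that ran from 46.2% to 72.5% over the alternative fits, so no direction is drawn from it. The median standard error of a log2 change was 0.18. The 95% interval of the change lay inside 2-fold in either direction for 11529 genes (83.5%), and inside 1.5-fold for 56.7% of the genes tested. Among the 9334 genes with a mean of at least 10 CPM, 94.7% had an interval inside 2-fold. These intervals describe the whole tissue of each library, in which unedited cells can be present.

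Each of the genes named was chosen by the smallest unadjusted p in its direction. Genes entered this choice only with a mean of at least 1 CPM. They also needed at least 9 of 12 KO libraries on the same side of the CTRL median. A high count of such libraries was thus a condition of being named and is no further evidence. ENSGALG00000052557 lies on the minus strand of chromosome 4 at 21926876 to 21929479 of GRCg6a, with 3 exon records. It overlaps 2 other annotated genes, so its counts leave out any reads shared with them on that strand. Its log2 change was 0.50 (SE 0.12, edgeR p = 3.04e-04, adjusted p = 0.675). ENSGALG00000027899, on the plus strand of chromosome 4 at 2115235 to 2116290, had 9.48 CPM ± 2.85 (SD, n = 12) in KO and 5.54 CPM ± 1.54 (SD, n = 9) in CTRL. This was a log2 change of 0.77 (SE 0.20, edgeR p = 6.23e-04, adjusted p = 0.675), with 11 of 12 KO libraries above the CTRL median. ENSGALG00000015055, on the plus strand of chromosome 3 at 66523052 to 66554168 with 17 exon records, had a log2 change of -1.43 (SE 0.30, edgeR p = 9.70e-05, adjusted p = 0.675). ENSGALG00000002957, on the minus strand of chromosome 11 at 2036749 to 2043464 with 27 exon records, had 0.819 CPM ± 0.591 (SD, n = 12) in KO and 2.94 CPM ± 2.22 (SD, n = 9) in CTRL. Its log2 change was -1.83 (SE 0.43, edgeR p = 3.16e-04, adjusted p = 0.675), with 11 of 12 KO libraries below the CTRL median. CTRL replicates 1, 4 and 7 stood at 4.96, 5.49 and 6.61 CPM for this gene. The other controls lay at 0.512 to 2.45 CPM, within the KO range of 0.286 to 2.47 CPM.

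**Figure D1:**
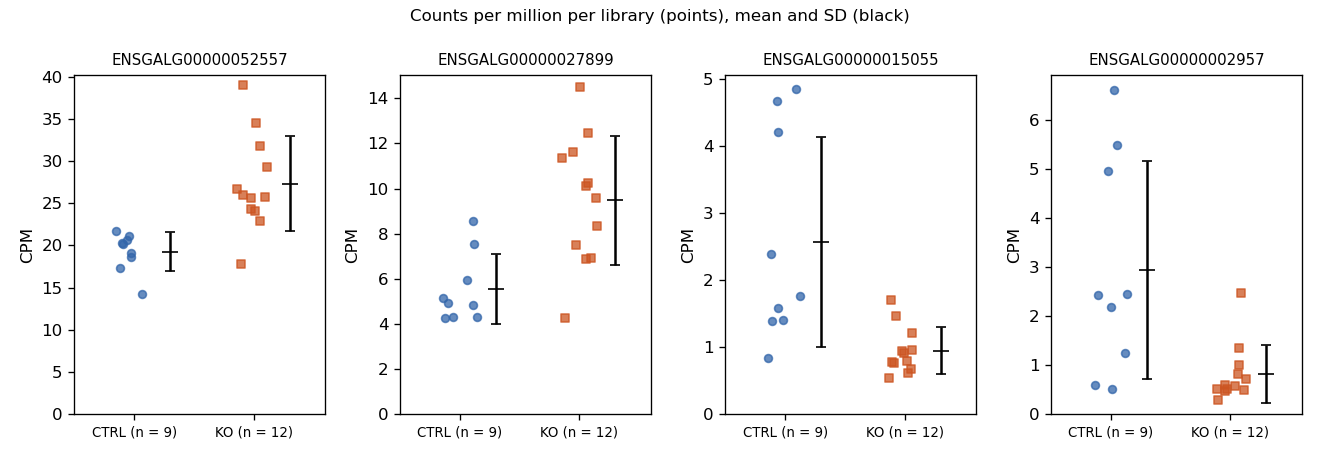
Level in CPM of the 4 named genes in each library (points, vertical axis from 0), with the group mean and SD in black beside them, for 9 CTRL and 12 KO libraries. The KO means of 27.3 and 9.48 CPM lie above the CTRL means of 19.3 and 5.54 CPM in the first pair, and the KO means of 0.949 and 0.819 CPM lie below 2.57 and 2.94 CPM in the other pair; none of the 4 passed the adjusted threshold.

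By chromosome, the groups that stood out in KO against CTRL libraries were genes of the W chromosome, with lower values, and genes of the Z chromosome and the mitochondrial genome, with higher values. In birds a W chromosome is carried by females, while males carry a pair of Z chromosomes. Of 35 groups, 6 passed camera with its preset correlation, and all 6 calls were lost with an estimated correlation (adjusted p = 0.860 for each). None of the 6 passed fry (adjusted p = 0.507 for each), which tests a group against no change rather than against the other genes. Adjusted over each group alone, 0 genes passed in these 6 groups. The 40 tested W genes had a median log2 change of -0.71 (adjusted p = 2.66e-13 with the preset correlation and 0.860 with an estimated one), and 0 of them had an unadjusted p under 0.05 by edgeR. The 619 tested Z genes had a median log2 change of 0.16 (adjusted p = 3.19e-09 with the preset correlation and 0.860 with an estimated one), with 64 genes higher and 8 lower at an unadjusted p under 0.05. The 25 mitochondrial genes, which encode parts of the respiratory chain and mitochondrial ribosomal and transfer RNAs, had a median log2 change of 0.21 (adjusted p = 1.31e-04 with the preset correlation and 0.860 with an estimated one), with 3 genes higher and 0 lower at that level. Smaller medians were found for the 70 genes of chromosome 32 (0.050, preset adjusted p = 0.00839), with 6 genes higher and 0 lower at that level, for the 65 genes of chromosome 16, which carries the major histocompatibility complex of the chicken (-0.14, preset adjusted p = 0.0422), with 1 higher and 7 lower, and for the 57 genes of chromosome 31 (-0.16, preset adjusted p = 0.0422), with 0 higher and 8 lower. For these 3 groups too the adjusted p was 0.860 with an estimated correlation. The other 29 groups did not pass with the preset correlation.

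W transcripts were present in some embryos and nearly absent in others. They made up 0.180% to 0.239% of counts in 15 libraries and 0.00202% to 0.00455% in the other 6. The 15 libraries with W transcripts were 8 of 9 CTRL and 7 of 12 KO libraries, a difference that did not pass Fisher's exact test (2-sided p = 0.178). The 6 libraries with little W signal were CTRL replicate 9 and KO replicates 1, 3, 5, 9 and 10. In CTRL replicate 9 the W share was 0.00455% (95% Wilson interval 0.00424% to 0.00489%). Z transcripts made up 2.97% to 3.24% of counts in these 6 libraries and 1.83% to 2.30% in the 15 others. Mean W shares were 0.187% ± 0.0704 (SD, n = 9) in CTRL and 0.124% ± 0.108 (SD, n = 12) in KO (exact permutation p = 0.156). Mean Z shares were 2.25% ± 0.393 (SD, n = 9) in CTRL and 2.53% ± 0.502 (SD, n = 12) in KO (exact permutation p = 0.203). With the summed log2 CPM of W genes in the model, the median log2 change of Z genes was -0.020 (camera adjusted p = 0.953).

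**Figure D2:**
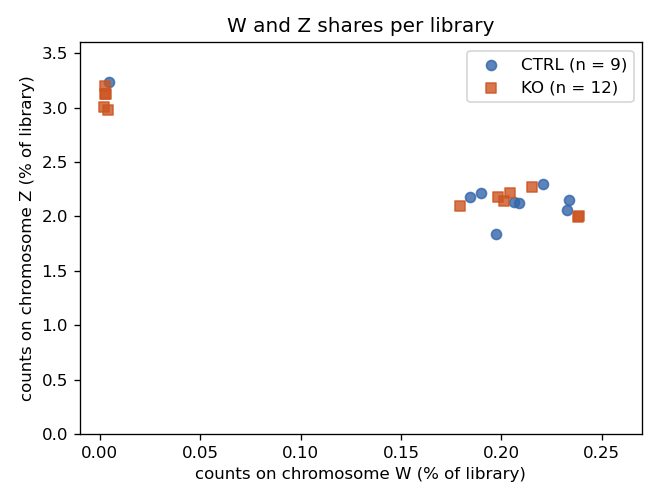
Share of each library's counts on chromosome W (horizontal axis, percent) against the share on chromosome Z (vertical axis, percent), 1 point per library, for 9 CTRL and 12 KO libraries. The 6 libraries at the left, 1 CTRL and 5 KO, have Z shares of 2.97% to 3.24%, and the 15 at the right have Z shares of 1.83% to 2.30%.

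Mitochondrial transcripts made up 7.98% ± 1.49 of counts (SD, n = 9) in CTRL and 9.08% ± 2.17 (SD, n = 12) in KO libraries, a difference within the spread between libraries (exact permutation p = 0.211). The highest shares in KO were 11.5%, 11.1% and 14.3%, in replicates 4, 5 and 6, and the other 9 KO libraries lay at 6.72% to 9.18%, within the CTRL range of 6.68% to 11.0%. KO replicates 4, 5 and 6 also lay highest of the KO libraries on the second principal component of autosomal genes, at 43.9, 42.5 and 45.2. The 20 genes with the most counts took 14.6% ± 1.56 (SD, n = 9) of the counts in CTRL and 15.3% ± 2.31 (SD, n = 12) in KO (exact permutation p = 0.483).

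Among autosomal genes, the largest axis of variation separated a pair of libraries, 1 from each group, from the others. The leading component held 34.7% of the variance; CTRL replicate 1 lay at -95.9 and KO replicate 8 at -111, and the other 19 libraries between -36.0 and 47.3. No difference between the groups passed the test on this component (exact permutation p = 0.936) or on the next, which held 16.5% (exact permutation p = 0.509). On the component after these, with 9.21% of the variance, the group means were 12.4 ± 24.6 (SD, n = 9) in CTRL and -9.30 ± 12.5 (SD, n = 12) in KO (exact permutation p = 0.0148, adjusted p = 0.148 over 10 measures), and CTRL replicate 1 lay highest of the 21 libraries, at 50.8. CTRL replicate 1 lacked 54 genes that had a median of at least 10 CPM in the other 19 libraries, and KO replicate 8 lacked 58. The lists shared 43 genes. Independent lists would share 0.341, but both libraries were set apart after the data were seen, so this number is no fair benchmark. A gene on the minus strand of chromosome 1 at 85383662 to 85470351 had a median of 2609 CPM in the other 19 libraries, 0.334 CPM in CTRL replicate 1 and 16.7 CPM in KO replicate 8; it was chosen after its values were seen. With both libraries left out, edgeR still called 0 genes.

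**Figure D3:**
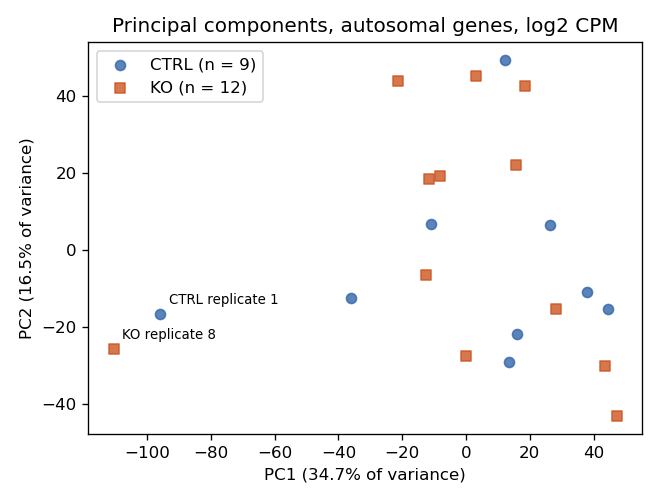
The first and second principal components of log2 CPM of autosomal genes, with the share of variance on each axis, 1 point per library, for 9 CTRL and 12 KO libraries. CTRL replicate 1 and KO replicate 8 lie at -95.9 and -111 on the horizontal axis, apart from the other 19 libraries between -36.0 and 47.3.

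The 54 genes missing from CTRL replicate 1 summed to 105 CPM in that library and 245 CPM in KO replicate 8, against 5948 to 17933 CPM in the other 19 libraries. Genes at least 8 times above the median of the other 19 libraries numbered 79 in CTRL replicate 1 and 79 in KO replicate 8, with 26 shared. Independent lists would share 0.452, again no fair benchmark for libraries picked after the data were seen. The 79 genes of CTRL replicate 1 summed to 4927 CPM there and 1939 CPM in KO replicate 8, against 209 to 1471 CPM in the other 19, where CTRL replicate 7 was highest. In the other 19 libraries, the difference in log2 summed CPM between 8 CTRL and 11 KO libraries did not pass the test for the missing genes (exact permutation p = 0.782) or the high genes (exact permutation p = 0.722).

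**Figure D4:**
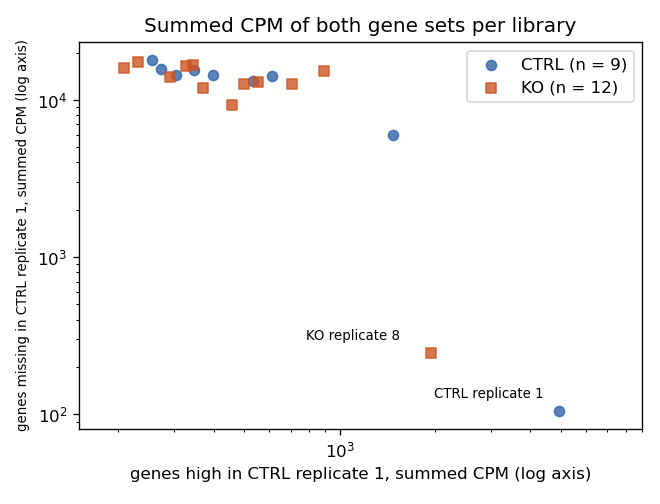
Summed CPM of the 79 genes high in CTRL replicate 1 (horizontal log axis) against summed CPM of the 54 genes missing from it (vertical log axis), 1 point per library, for 9 CTRL and 12 KO libraries. KO replicate 8 lies nearest to CTRL replicate 1, from whose counts both gene sets were chosen, and the other 19 libraries lie at 5948 to 17933 CPM on the vertical axis.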

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

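The tests on W and Z transcripts and on CTRL replicate 1 and KO replicate 8 were chosen after the results were seen, and the random splits of the libraries were planned before their results. Of 17 values per library examined in the CTRL group, 6 had 1 library far from the other 8. The chance rate of about 1 in 20 per value is no fair measure of this count, because the values were not independent. W and Z shares went together, and several values concerned CTRL replicate 1. The KO group, with more than 10 libraries, was not examined this way. CTRL replicate 9 was far below the other controls in W share (0.00455%) and far above them in Z share (3.24%). CTRL replicate 1 was far above them in the number of abundant genes it lacked (54), in the summed CPM of the genes high in it (4927 CPM, genes chosen from that library) and in the SD of its log2 differences from the median library (1.05). CTRL replicate 3 was far above the other controls on the second principal component, at 49.3, where KO replicates 4, 5 and 6 lay at 43.9, 42.5 and 45.2.

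Mean W shares were lower and mean Z shares higher in KO libraries, without passing exact permutation tests (p = 0.156 and 0.203), and 5 of 12 KO and 1 of 9 CTRL libraries had little W signal. A loss of W transcripts alone through the knock-out is argued against by the Z shares, whose lowest value among the 6 libraries with little W signal was 2.97%, above the highest of the 15 others (2.30%). Little W signal was also seen in CTRL replicate 9 (0.00455%), and 7 of 12 KO libraries held W transcripts. W shares of 0.180% to 0.239% and of 0.00202% to 0.00455% split the libraries into the same sets as the Z shares, without overlap. Female and male embryos would give this pattern. Unequal numbers of male and female embryos in the groups are a candidate explanation, as the median log2 change of Z genes was 0.16 without and -0.018 with the log2 W share as covariate, although Z shares had been seen to follow W shares before this fit. The labels give no sex of the embryos, and Fisher's exact test of the numbers of libraries gave p = 0.178, so an unequal draw by chance stays open. Whether targeting MOXD1 affects male and female embryos differently was not tested.

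CTRL replicate 1 and KO replicate 8 lacked genes that were abundant in the other 19 libraries. Low depth or few detected genes are argued against, since the lower of both libraries had 12718 genes at 1 CPM and the lowest of the other 19 had 12473. The knock-out is argued against, since a CTRL library lacked 43 of the 58 genes missing from KO replicate 8. Another tissue in these libraries may account for the pattern, as 26 of the genes high in one were also high in the other. Independent lists would share 0.452, but both libraries were picked after the data were seen because they stood apart. An overlap above that number could therefore hardly fail, and it does not tell another tissue from another shared difference. Whether either library came from outside the series was not tested, and these values do not decide it. An exchange of labels between the groups would not by itself make a library lack these genes, which summed to at least 5948 CPM in each of the other 19. Whether any labels were exchanged cannot be read from these values.

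For the count of genes at an unadjusted p under 0.05 and the count of chromosome groups, chance could not be excluded by 100 splits of the 21 libraries into 9 and 12, the real one included. For genes past the threshold the splits decide nothing, since any split (100 of 100) gives at least the real 0; the highest other split gave 5. The real 977 genes at an unadjusted p under 0.05 were reached in 20 of 100 splits, with a highest other count of 2571. What gave the high counts was not tested. As many as the real 6 chromosome groups passed camera with its preset correlation in 26 of 100 splits, with 17 in the highest other, and at least 1 group passed in 82 of 100.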

How the results depend on the processing

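Fits without CTRL replicate 1 and KO replicate 8, the log2 W share as covariate, and the counts at an unadjusted p under 0.05 and by chromosome, were chosen after seeing the data; the planned MOXD1 level and the 43 planned gene lists were not run. The number of genes past the threshold was 0 in each of the 40 alternatives. The 4 named genes had the same direction, and did not pass, in each of 38 alternatives (adjusted p 0.0867 to 0.986). Their direction could hardly change, since they were chosen by the smallest p in these same libraries, so it is no further evidence. The 977 genes at an unadjusted p under 0.05 became 1576 without a filter on low counts, where more genes were tested, 543 with the summed log2 CPM of W genes as covariate, 592 with the log2 W share as covariate, 1705 with 2 surrogate variables, 1517 with the replicate number of the title as a block, and 452 without both libraries and with the log2 W share; the cause was not tested. Leaving out each library gave 682 to 1337. Replicate numbers did not meet the rule for pairing, a correlation over 0.1 in every pair: same-numbered deviations correlated at -0.432 to 0.428 over 9 title numbers (mean 0.108, 6 over 0.1, 1 best with its own number) and at -0.207 to 0.428 over 8 description numbers (mean 0.185, 6 over 0.1, 2 best with their own), against a mean of 0.0039 over all pairs across groups; the block by description number gave 1089 genes. The 6 chromosome groups became 3 with 2 surrogate variables, 2 without genes on Z and W, 0 with an estimated correlation, 0 with fry and 3 without both libraries and with the log2 W share. Leaving out each library gave 3 to 6 groups, with 3 without CTRL replicate 9. The Z median was reversed with the summed W covariate (-0.020) and with the log2 W share (-0.018), also without both libraries (-0.028), and was 0.26 without CTRL replicate 9. The W median was 0.11 with the summed W covariate, which is made from the same genes and so takes their change out, -0.11 with the log2 W share and -0.14 with it and without both libraries. It was -2.92 with limma voom, and -1.62 and -3.07 with the number of the title or the description as a block. The mitochondrial call was lost with 2 surrogate variables (median 0.028), and its median was 0.13 without a filter on low counts, 0.14 without CTRL replicate 6, 0.12 without KO replicate 5 and 0.13 without KO replicate 9. Chromosomes 16, 31 and 32 did not pass in 22, 17 and 7 of 39 alternatives. Chromosome 16 did not pass without any 1 of CTRL replicates 1, 3, 4, 8 and 9 and KO replicates 1, 2, 7, 8, 10 and 11 (medians -0.15 to -0.021), and chromosome 31 without any 1 of CTRL replicates 3, 4 and 9 and KO replicates 1, 6, 7, 8 and 9 (medians -0.19 to -0.036). Chromosome 32 did not pass without CTRL replicate 7 (0.042), CTRL replicate 9 (0.033) or KO replicate 10 (0.078), and its median was 0.13 without CTRL replicate 3, 0.10 without CTRL replicate 4 and 0.032 without CTRL replicate 8. At the depth, number and spread of these libraries, simulated 1.5-fold changes were called in 39.4% of changed genes, all with a mean of at least 1 CPM. These runs also held 2-fold and 4-fold changes, so the share need not hold for 1.5-fold changes alone. Depth alone was not varied.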

Other observations

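The test of a graded relation between both gene sets, and the test of neighbouring genes, were chosen after the data were seen. Genes of both sets lay next to each other on chromosomes more often than random genes. Among the 54 genes missing from CTRL replicate 1, 3 pairs were neighbours among tested genes, against a mean of 0.207 in 1000 random draws from genes with a median of at least 10 CPM. Among the 79 genes high in that library, 8 pairs were neighbours, against a mean of 0.436 in 1000 draws. The highest numbers in any draw were 2 and 4 pairs, and each permutation p of 0.000999 was the smallest that the draws can give. A gene on the plus strand of chromosome 3 at 43047577 to 43055477 had a median of 1700.3 CPM in the other 19 libraries, 11.4 CPM in CTRL replicate 1 and 21.4 CPM in KO replicate 8. A gene on the minus strand of chromosome 27 at 5243768 to 5247636 had a median of 930 CPM, against 0.286 and 6.11 CPM. Both were the next most abundant of the 43 shared missing genes after the one on chromosome 1, and were chosen after their values were seen.

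Over the other 19 libraries, a higher sum of the high genes went with a lower sum of the missing genes on the log2 scale (Pearson r = -0.711, permutation p = 0.00170; Spearman rho = -0.695, permutation p = 0.00119). Without CTRL replicate 7 and KO replicate 1, the farthest on the axis of high genes, r was -0.609 (permutation p = 0.00821). Within CTRL r was -0.922 (n = 8, exact permutation p = 0.00161), and -0.822 without CTRL replicates 3 and 7 (n = 6, exact permutation p = 0.0486). Spearman rho without CTRL replicates 3 and 7 was -0.829 and did not pass (exact permutation p = 0.0583). Within KO r was -0.390 (n = 11, permutation p = 0.235), and -0.657 without KO replicates 1 and 4 (n = 9, exact permutation p = 0.0539), so that neither passed within KO. A graded amount of the same other tissue in the 19 libraries may give such a relation, but the values within KO leave this open. This was the only relation between measures computed across libraries, but it was tested on several sets of libraries by Pearson and Spearman correlation. No adjustment over these tests was made, so p-values near 0.05 are weak evidence.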
